A study of Homo sapiens with 12 samples.

How the data were processed

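Messenger RNA was sequenced from 12 libraries of 3 human colorectal cancer cell lines, DLD1, HCA7 and HT29. In each line 2 libraries came from wild-type (WT) cells and 2 from cells with a furin knockout (KO). Furin is a protease of the secretory pathway that cleaves precursor proteins at basic sites. Per the labels, RNA was purified with NucleoSpin RNA and libraries were made with the TruSeq Stranded mRNA kit. The labels do not say whether a KO culture is a clone or a pool, nor whether the 2 replicates of a group are separate cultures, so the p-values measure only the spread between these samples. The 2 DLD1 KO libraries differed little beyond counting error, with a chi-square per degree of freedom of 1.32. In the other groups it was 2.23 to 7.93. For well expressed genes the SD of the log2 difference between replicates was 0.140 to 0.189 over the groups. These values do not tell whether replicates are separate cultures.

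The authors' notes name TopHat2, HTSeq, DESeq and the hg19 genome. Their versions, the gene annotation and the strand setting are not given in the sources used here. The deposited files hold, for each of 56638 gene symbols, a signal that is a read count divided by 1 size factor per library. This was checked on the files: in each of the 12 libraries 100% of the values were whole multiples of the smallest step, with a largest departure of 8.59e-10 against a tolerance of 1e-06. One read was worth 0.794 to 1.25 units, and the recovered totals were 10244000 to 19466206 reads per library. Divided by the median-of-ratios factors of DESeq2 1.42.0, the deposited size factors were nearly constant within each line (1.01 to 1.02 in DLD1, 0.867 to 0.872 in HCA7 and 1.09 to 1.10 in HT29) but differed between lines, so KO and WT of a line share a scale while levels in different lines depend on the scaling. Gene names are those of an older annotation (IL8 is CXCL8, CYR61 is CCN1, CTGF is CCN2, PVRL3 is NECTIN3). The annotation at hand, GENCODE v29, belongs to a later genome build, so chromosome names and gene order were taken from it and no coordinates are given.

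The values, with 1 added, were put on the log2 scale and fitted with limma 3.58.1 (trended prior, R 4.3.3) in a model with a term for each of the 6 groups over all 12 libraries, which left 6 residual degrees of freedom and gave 6.32 prior degrees. KO was compared with WT in each line, and the KO effects were compared between each pair of lines as interaction contrasts. An additive model with cell line and KO gave the average effect. Its spread pools how far the KO effect differs between lines with the spread between replicate libraries. Its SE and p-values therefore do not measure the spread between lines alone. A gene was tested in a contrast when it reached 10 in at least 2 libraries of each line in that contrast. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05 (limma, two-sided). Folds against a group with no reads were computed against 3 reads over the group, and ratios with 1 to 3 reads in a group are given with an exact 95% interval. Both cover counting error only.

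The comparisons, 25 gene lists with 391 genes and the rule for naming genes were fixed before the data were examined. An edgeR test on counts had been planned. Because the deposited values are scaled, limma became the main test and edgeR 4.0.16 on the recovered reads an alternative. The lists were tested with camera (two-sided, preset correlation 0.01, Benjamini-Hochberg over the lists of a contrast), with camera using an estimated correlation, and with fry, for lists with at least 3 measured members. With an estimated correlation camera tests on the residual degrees of freedom alone, so its p-value can rise where the correlation does not. Named genes are FURIN, and for each line the 10 highest and 10 lowest called fold changes among genes with a mean log2 CPM of at least 3, both KO libraries on the same side of both WT libraries, and no clone-based, antisense or pseudogene symbol. They also include up to 4 called members of each list by smallest adjusted p (the 2 most abundant members where none was called), the 8 highest and 8 lowest average effects with 1 sign in all 3 lines, and the 3 highest and 3 lowest differences between each pair of lines. Single members that moved against the rest of their list are named too, chosen after their values were seen. Genes whose reads are shared with near copies (UGT1A6, ALPP, CYP4F3, HIST1H2BK) were left out, and the HLA, metallothionein and IFIT genes are kept with that limit. Some genes that the rule picks are not reported.

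The pipeline was tested on simulated data with the depth and spread of these libraries. A first filter, 10 in at least 2 of all 12 libraries, gave more than 5% false calls there. Several remedies were compared on simulated data and the filter per contrast was chosen, after the real counts under the first filter had been seen. The first filter is kept as an alternative. With the chosen filter the share of false calls was 4.93% in DLD1, 3.01% in HCA7, 4.79% in HT29, 1.64% for DLD1 against HCA7 and 2% for the average. Simulated changes were in DLD1 alone or of the same fold in all 3 lines, in genes well expressed in each line. For the average, genes changed in DLD1 alone counted neither as false nor as changed. The 2% therefore does not cover KO effects that differ between lines. Of simulated 2-fold changes, 99% were called in DLD1, 96% in HCA7 and 92% in HT29; of 1.3-fold changes, 50%, 42% and 46%. None of 50 simulated unchanged lists had a camera p under 0.05. Their genes were simulated independently of one another, so this check does not cover lists of correlated genes. The edgeR test gave false shares of 6.70%, 7.50% and 6.99%.

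Alternatives were other scalings (TMM, DESeq2 median of ratios, upper quartile), pseudocounts of 0.5 and 5, no low-value filter, the filter over all libraries, edgeR, DESeq2 and limma-voom on the recovered reads, a replicate block, fits on the compared lines alone, the mean of the 3 within-line effects, a TREAT test of edgeR against a fold of 1.2, and leaving out each library in turn. Groups of 2 are too small for an outlier test. No library was excluded.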

Results

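The data are gene-level mRNA values of 12 libraries, 2 WT and 2 furin KO libraries in each of the colorectal cancer lines DLD1, HCA7 and HT29. In DLD1 the WT libraries held 15675692 and 13115310 counted reads and the KO libraries 13757333 and 10244000. In HCA7 they held 13020851 and 19466206 (WT) and 13852194 and 18003649 (KO), and in HT29 12753359 and 16347713 (WT) and 11203320 and 11252179 (KO). The share of reads from mitochondrially encoded genes was 4.63% and 4.01% in DLD1 WT and 5.77% and 5.79% in DLD1 KO, 6.31% and 5.32% in HCA7 WT and 4.86% and 5.17% in HCA7 KO, and 7.07% and 7.31% in HT29 WT and 6.44% and 6.65% in HT29 KO. The ribosomal gene RNA28S5 took 0.336% of the reads of DLD1 WT replicate 1 and 0.898% to 1.60% in the other 11 libraries. Changes are given as log2 fold changes of KO against WT ± SE, from 2 KO and 2 WT libraries, with adjusted p-values from limma. Levels are deposited values, reads divided by the size factor of the library.

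FURIN, the gene targeted in the KO cells, was lower in all 3 lines. In DLD1 its level went from 1405 and 1487 in WT to 704 and 674 in KO, a 2.10-fold lower level (-1.07 ± 0.07, limma adjusted p = 5.69e-07). It was 2.70-fold lower in HCA7 (1511 and 1385 to 555 and 517; -1.43 ± 0.07, limma adjusted p = 1.44e-08) and 2.91-fold lower in HT29 (954 and 1065 to 357 and 336; -1.54 ± 0.07, limma adjusted p = 4.28e-08). FURIN mRNA at 47.7%, 37.1% and 34.4% of the WT level was left in DLD1, HCA7 and HT29 KO. The files hold gene totals, so whether the remaining transcripts carry an edit, and the furin protein itself, were not analysed here.

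**Figure D1:**
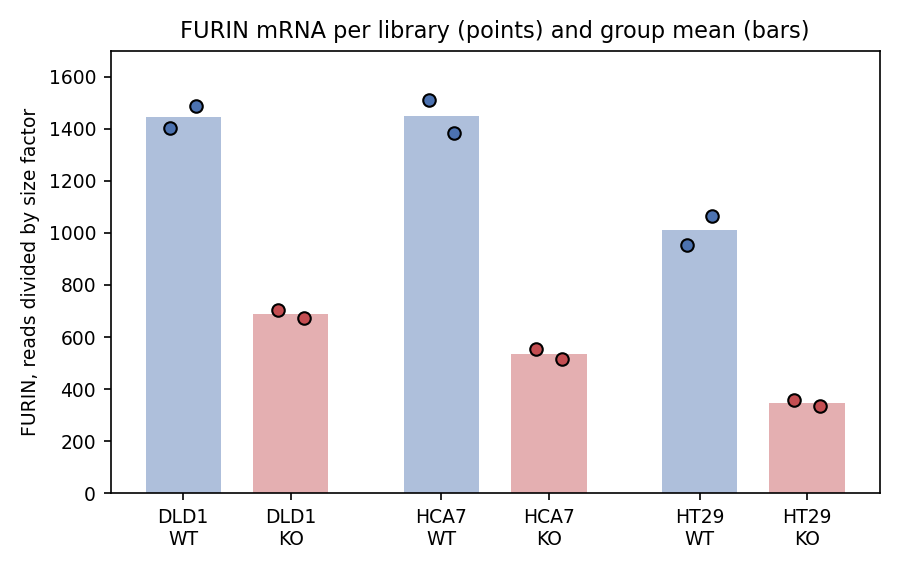
FURIN mRNA in the 12 libraries, in reads divided by the size factor of the library, with a point per library and a bar for the mean of the 2 libraries of a group. In each line both KO points lie below both WT points, and KO levels range from 336 to 704.

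In DLD1, the comparison asks what differs between KO and WT cells of this line. The strongest rise among the named genes was that of LAMA2, a laminin chain of basement membranes, from 129 and 116 to 1887 and 1882 (15.3-fold; 3.94 ± 0.22, limma adjusted p = 1.17e-07). Also higher were the integrin ITGA9 (3.22 ± 0.17), the matrix glycoprotein TNC (2.25 ± 0.22), the membrane metalloprotease MMP14 (1.77 ± 0.17), the chloride channel CFTR (2.68 ± 0.07), the elongation factor EEF1A2 (2.75 ± 0.18), SH3BGRL (2.24 ± 0.13), the vasoconstrictor precursor EDN1 (2.03 ± 0.06) and the microtubule-binding MAP2 (1.79 ± 0.27). LCN2, which binds bacterial siderophores, fell from 733 and 779 to 95.4 and 93.8 (7.91-fold lower; -2.98 ± 0.06, limma adjusted p = 2.92e-11). The protease CTSZ (-2.63 ± 0.06), the chemokine IL8 (-2.45 ± 0.28), the sphingosine 1-phosphate transporter SPNS2 (-2.35 ± 0.06), the imprinted RNA H19 (-1.79 ± 0.38), the transcription factor NFIB (-1.72 ± 0.06), the ephrin receptor EPHB2 (-1.58 ± 0.10), SLC44A4 (-1.53 ± 0.19) and the follistatin-like FSTL3 (-1.53 ± 0.13) fell too.

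Among the lists in DLD1, the NF-kB and chemokine genes showed the lowest median. Of 14 measured members 11 fell, none rose and 3 did not pass (median -1.11, camera adjusted p = 1.39e-07), and adjusted over the list alone 13 fell. CXCL1 went from 108 and 97.4 to 15.9 and 16.3 (-2.60 ± 0.20), CCL20 changed by -3.46 ± 0.37 and CXCL3 by -1.30 ± 0.16, all neutrophil or lymphocyte attractants. The lymphotoxin gene LTB had 45 reads in WT and 0 in KO, at least 12.8-fold lower. With LTB at that bound the list median was unchanged at -1.11. This call held with an estimated correlation (adjusted p = 0.0196), the only one of the 8 camera calls in DLD1 that did.

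Of 13 mitochondrially encoded genes 9 rose in DLD1 (MT-ATP6 0.68 ± 0.10, MT-CO3 0.55 ± 0.09). Their median was 0.35, with camera adjusted p = 0.000559 and adjusted p = 0.418 with an estimated correlation. Adjusted over the list alone 9 rose, and none fell in either count. Of 19 interferon-stimulated genes 6 rose, also 6 adjusted over the list alone (OAS1 0.77 ± 0.10, IFI6 1.02 ± 0.18). This list's median was 0.22 (camera adjusted p = 0.0305, and adjusted p = 0.309 with an estimated correlation). Of 24 proliferation genes 9 fell and none rose, with the same count adjusted over the list alone (the replication licensing factor MCM3 -0.52 ± 0.05, the mitotic kinase CDK1 -0.25 ± 0.05). With a median of -0.13 the camera adjusted p was 0.00495, and 0.418 with an estimated correlation. Of 18 ATF4 targets, genes of amino acid supply, 5 fell and none rose, again the same adjusted over the list alone (SLC7A5 -0.47 ± 0.05, MTHFD2 -0.45 ± 0.06). Their median was -0.20, with camera adjusted p = 0.0231 and adjusted p = 0.418 with an estimated correlation. Hypoxia genes had 6 lower and 1 higher, ADM (0.54 ± 0.14), of 16, 7 and 1 adjusted over the list alone (LDHA -0.59 ± 0.06, PGK1 -0.46 ± 0.06, VEGFA -0.31 ± 0.06). The list had a median of -0.21, camera adjusted p = 0.0433, and adjusted p = 0.309 with an estimated correlation. Of 18 cholesterol synthesis genes 8 rose and 2 fell, 9 and 3 adjusted over the list alone (INSIG1 0.69 ± 0.05, DHCR7 0.42 ± 0.05, HMGCS1 0.40 ± 0.05). This list's median was 0.08 (camera adjusted p = 0.0305, and adjusted p = 0.354 with an estimated correlation). With upper-quartile scaling it was 0.01, and the median of all tested genes moved from -0.005 to -0.067. Of 7 proprotein convertases, the enzyme family of furin, 4 fell, among them FURIN, PCSK5 (-0.67 ± 0.13) and PCSK7 (-0.36 ± 0.08), and MBTPS1 rose (0.20 ± 0.05), 5 and 2 adjusted over the list alone (median -0.36, with camera adjusted p = 0.0305 and estimated correlation adjusted p = 0.309). The list holds the targeted gene, and without FURIN it was not called (median -0.25, camera adjusted p = 0.142).

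Lists whose camera test did not pass in DLD1 held changed members as well. The known furin substrates had 6 higher and 3 lower of 20 (7 and 3 adjusted over the list alone, camera adjusted p = 0.0801), among them LRP1 (1.18 ± 0.07), the insulin receptor INSR (0.68 ± 0.07) and TGFB1 (0.86 ± 0.10). ERK pathway output had 9 lower and 2 higher of 18 (11 and 4 adjusted over the list alone, camera adjusted p = 0.0801), with the phosphatase DUSP4 (-0.80 ± 0.10) and the cyclin CCND1 (-0.32 ± 0.04). The ER chaperone list had 3 lower and 2 higher of 17 (4 and 2 adjusted over the list alone, camera adjusted p = 0.589), and HSP90B1 of that list fell by 1.02 ± 0.06 on the log2 scale. The colonocyte list had 3 higher and 2 lower of 5 with the same counts adjusted over the list alone (camera adjusted p = 0.544): the keratin KRT20 rose (1.63 ± 0.11), and VIL1, which bundles actin in microvilli, fell (-2.65 ± 0.12). The list's median was 0.57 and its mean -0.07.

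Over all 13857 genes tested in DLD1, 4095 changed (29.6%), 1818 higher and 2277 lower, and 527 of them by at least 2-fold (316 higher, 211 lower, limma). The share of higher genes among those called was 44.4%, and 30.1% with upper-quartile scaling. The count was 2572 without WT replicate 2, 2685 without KO replicate 1 and 2255 without KO replicate 2, where the lone library is assumed to vary like the other groups. Without WT replicate 1, 1197 were higher, and with no low-value filter 361 were at least 2-fold lower.

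In HCA7, the same question was asked. EPHB6, an ephrin receptor without kinase activity, rose from 42.2 and 36.7 to 653 and 712 (16.9-fold; 4.08 ± 0.09, limma adjusted p = 2.59e-11). Higher as well were the microtubule-associated DPYSL3 (3.78 ± 0.14), the actin bundler FSCN1 (3.55 ± 0.12), the actin-severing SCIN (3.21 ± 0.18), RGL3 (3.56 ± 0.09), GPRIN3 (3.21 ± 0.18), the secreted NELL2 (2.84 ± 0.28) and the phospholipid-binding ANXA1 (2.73 ± 0.09). The transcription factor MYRF fell from 1732 and 1712 to 186 and 231 (8.28-fold lower; -3.05 ± 0.08, limma adjusted p = 1.09e-10). Also lower were acetylcholinesterase ACHE (-3.23 ± 0.42), the sortilin-family receptor SORCS2 (-3.16 ± 0.29), the proton pump subunit ATP6V1C2 (-3.11 ± 0.18), CORO2A (-3.05 ± 0.18), the netrin receptor NEO1 (-2.95 ± 0.10), the adaptor SH2B3 (-2.67 ± 0.14), the gut glutathione peroxidase GPX2 (-2.64 ± 0.28), LCN2 (-2.52 ± 0.06) and AUTS2 (-2.50 ± 0.22).

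The NF-kB and chemokine genes fell in HCA7 too, 13 of 14 lower and 1 higher, also adjusted over the list alone (median -0.98, camera adjusted p = 1.67e-06). IL32 went from 391 and 359 to 46.2 and 33.8 (-3.21 ± 0.24), IL8 from 240 and 223 to 19.2 and 41.6 (-2.98 ± 0.28), and NFKB2 changed by -0.86 ± 0.07, while the adhesion gene ICAM1 rose (1.05 ± 0.10). Of 16 p53 targets 14 rose and none fell, 15 adjusted over the list alone (median 0.57, camera adjusted p = 5.04e-08), with TP53I3 (1.12 ± 0.09), the death receptor FAS (1.10 ± 0.10), ZMAT3 (0.78 ± 0.10) and the DNA repair gene XPC (0.58 ± 0.07). Of 18 cholesterol synthesis genes 12 fell and none rose, 14 adjusted over the list alone (median -0.27, camera adjusted p = 1.67e-06), with HMGCS1 (-0.68 ± 0.05) and INSIG1 (-0.58 ± 0.05). Of 14 WNT targets 8 rose and 1, ZNRF3, fell (-0.35 ± 0.04), also adjusted over the list alone (median 0.54, camera adjusted p = 0.000386), with the WNT inhibitor NOTUM (2.64 ± 0.25), EPHB3 (1.69 ± 0.18), the stem cell receptor LGR5 (0.57 ± 0.05) and CD44 (0.51 ± 0.06). These 4 calls held with an estimated correlation (adjusted p = 0.0162 for NF-kB, 0.0162 for p53 targets, 0.0492 for cholesterol synthesis and 0.049 for WNT targets), and the other 8 of the 12 camera calls in HCA7 did not.

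Of 12 YAP targets 7 rose and 1, the coagulation receptor F3, fell in HCA7 (-0.34 ± 0.10), 9 and 1 adjusted over the list alone (the ectonucleotidase NT5E 1.62 ± 0.13, CTGF 1.24 ± 0.13, ANKRD1 1.90 ± 0.30). With a median of 0.76 the camera adjusted p was 0.000386, and 0.0664 with an estimated correlation. Of 18 ATF4 targets 11 fell and 1, ATF3, rose (0.56 ± 0.10), also adjusted over the list alone. The serine synthesis enzyme PHGDH went from 2535 and 2812 to 655 and 637 (-2.05 ± 0.07), DDIT4 by -1.62 ± 0.09 and asparagine synthetase ASNS by -1.14 ± 0.07 (median -0.45, with camera adjusted p = 2.27e-06 and estimated correlation adjusted p = 0.0834). Of 13 mitochondrially encoded genes 11 fell, 12 adjusted over the list alone (MT-ND3 -0.59 ± 0.08, MT-ATP6 -0.57 ± 0.10). Their median was -0.41, with camera adjusted p = 0.000178 and adjusted p = 0.38 with an estimated correlation. Of 24 proliferation genes 12 fell and none rose, 14 adjusted over the list alone (CCNA2 -0.33 ± 0.05, MCM6 -0.37 ± 0.06). The list had a median of -0.16, camera adjusted p = 0.00036, and adjusted p = 0.38 with an estimated correlation. ERK pathway output had 9 lower and 4 higher of 18, 10 and 4 adjusted over the list alone (DUSP5 -1.15 ± 0.10, ETV4 -0.89 ± 0.07, PHLDA1 0.64 ± 0.06). This list's median was -0.27 (camera adjusted p = 0.0121, and adjusted p = 0.38 with an estimated correlation). MHC class I and antigen processing genes had 7 lower of 12, also adjusted over the list alone (the immunoproteasome subunits PSMB8 -0.51 ± 0.08 and PSMB9 -1.32 ± 0.25). With a median of -0.28 the camera adjusted p was 0.00259, and 0.0664 with an estimated correlation. Matrix and invasion genes had 6 higher and 3 lower of 12, also adjusted over the list alone (the laminin chain LAMA3 2.26 ± 0.06, the integrin ITGB6 1.62 ± 0.10, PLAUR 1.35 ± 0.13). Their median was 0.26, with camera adjusted p = 0.0219 and adjusted p = 0.1 with an estimated correlation. Of 4 metallothionein genes 2 fell, also adjusted over the list alone (MT2A -0.94 ± 0.16). The list had a median of -0.67, camera adjusted p = 0.0411, and adjusted p = 0.146 with an estimated correlation; MT1E had 53 reads in WT and 0 in KO, at least 17.7-fold lower.

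Among the known furin substrates in HCA7, 5 rose and 7 fell of 19 (6 and 8 adjusted over the list alone, camera adjusted p = 0.893), with the growth factors TGFB2 (2.99 ± 0.15), TGFB1 (1.80 ± 0.10) and BMP4 (1.21 ± 0.05) higher and the receptor IGF1R lower (-0.59 ± 0.06). Their median was -0.03 and their mean 0.16. Of 7 proprotein convertases 1 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.518): PCSK5 rose (0.78 ± 0.13), and FURIN and PCSK6 (-0.46 ± 0.05) were among those that fell. Here the median was 0.11 and the mean -0.16. Interferon-stimulated genes were not called as a list in HCA7, with 3 higher and 4 lower of 16, also adjusted over the list alone (median -0.01, camera adjusted p = 0.682). Of these IFI27 had 26 reads in WT and 3 in KO (ratio 8.71, 95% interval 2.67 to 44.9). Some genes were nearly absent from HCA7 KO: GRAMD1B had 338 reads in WT and 0 in KO, at least 113-fold lower, MYADM 951 and 1 (ratio 955, 95% interval 171 to 37778) and ATP2C2 400 and 1 (ratio 402, 95% interval 71.7 to 15912).

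Of 13788 genes tested in HCA7, 4427 changed (32.1%), 2057 higher and 2370 lower, 1015 of them by at least 2-fold (554 higher, 461 lower, limma). The share of higher genes was 46.5%, and 35.9% with upper-quartile scaling. The count was 2751 without KO replicate 1 and 2831 without KO replicate 2, and 1523 were lower without WT replicate 1.

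In HT29, the same question was asked. The glypican GPC4, a heparan sulfate proteoglycan of the cell surface, was 10.2-fold lower (-3.35 ± 0.15, both KO libraries below both WT libraries, limma adjusted p = 3.34e-08). Lower as well were ANXA13 (-2.83 ± 0.52), the adhesion protein CEACAM6 (-2.61 ± 0.25), the lectin REG4 (-2.38 ± 0.38), the sodium-glucose cotransporter SLC5A1 (-2.20 ± 0.29), the ferroxidase HEPH (-2.13 ± 0.12), CLEC3A (-3.42 ± 0.36) and RASL11A (-2.15 ± 0.19). SESN3, a stress-responsive sestrin, rose from 66.8 and 75.4 to 291 and 288 (4.04-fold; 2.01 ± 0.08, limma adjusted p = 1.56e-08). KIAA1549 (1.39 ± 0.07), HOXC6 (1.36 ± 0.22), PDZRN3 (1.32 ± 0.30), AKAP12 (1.28 ± 0.26), TEAD2 (1.21 ± 0.28), the chemokine receptor CXCR4 (1.15 ± 0.26), TCEAL4 (1.12 ± 0.08) and the protease BLMH (1.12 ± 0.09) rose.

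Of 18 cholesterol synthesis genes in HT29 10 fell and none rose, 14 adjusted over the list alone (SC5D -0.39 ± 0.05, INSIG1 -0.35 ± 0.05). This list's median was -0.22 (camera adjusted p = 2.65e-08, and adjusted p = 0.0973 with an estimated correlation). Of 17 ER chaperones 13 fell and none rose, also adjusted over the list alone (the transcription factor XBP1 -0.32 ± 0.05, CALR -0.29 ± 0.06, HSPA5 -0.29 ± 0.06). With a median of -0.25 the camera adjusted p was 5.12e-07, and 0.156 with an estimated correlation. Of 12 colonocyte differentiation genes 6 fell and none rose, 6 and 1 adjusted over the list alone: the intestinal transcription factors CDX2 (-1.74 ± 0.11) and CDX1 (-1.73 ± 0.22), the fatty acid binder FABP1 (-2.34 ± 0.30) and CEACAM5 (-1.67 ± 0.23). Their median was -0.48, with camera adjusted p = 0.00054 and adjusted p = 0.109 with an estimated correlation. Of 21 interferon-stimulated genes 5 rose and none fell, 8 adjusted over the list alone (IFI27 1.01 ± 0.27, MX1 0.82 ± 0.17, IFITM3 0.66 ± 0.14). The list had a median of 0.47, camera adjusted p = 0.000309, and adjusted p = 0.109 with an estimated correlation. Matrix and invasion genes had 7 lower and 2 higher of 12, 8 and 2 adjusted over the list alone (TNC -2.81 ± 0.22, S100A4 -0.92 ± 0.14). This list's median was -0.32 (camera adjusted p = 0.00184, and adjusted p = 0.109 with an estimated correlation). Of 7 proprotein convertases FURIN, PCSK5 (-0.43 ± 0.13) and PCSK6 (-0.20 ± 0.05) fell and none rose, also adjusted over the list alone (median -0.19, with camera adjusted p = 0.0257 and estimated correlation adjusted p = 0.145). Without FURIN, the targeted gene, the list was not called in HT29 (median -0.11, camera adjusted p = 0.26). In HT29 0 of these 6 calls held with an estimated correlation, where 6 lists had an unadjusted camera p under 0.05. By fry 11 lists were called.

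The NF-kB and chemokine genes did not pass camera as a list in HT29 (median -0.24, camera adjusted p = 0.26). Of 12 measured, LTB was higher and none lower, with 5 lower adjusted over the list alone. Fry, which does not compare a list with other genes, called the list lower (fry adjusted p = 0.0268). The known furin substrates had 3 higher and 5 lower of 20 (4 and 5 adjusted over the list alone, camera adjusted p = 0.26): TGFB1 fell from 288 and 309 to 76.7 and 67.4 (-2.04 ± 0.10), the integrin ITGAV (-0.44 ± 0.06) and the protease ADAM10 (-0.35 ± 0.05) fell, and INSR rose (0.45 ± 0.07). The TGF-beta and BMP targets had 2 higher and 3 lower of 12 (2 and 4 adjusted over the list alone, camera adjusted p = 0.0699), with TGFBI (-1.17 ± 0.06) and PMEPA1 (-0.58 ± 0.08) lower. BAMBI of that list had 131 reads in WT and 2 in KO (ratio 51.8, 95% interval 14.1 to 432). The p53 targets had 2 higher and 3 lower of 16 (2 and 4 adjusted over the list alone, camera adjusted p = 0.763), with GDF15 higher (0.59 ± 0.07).

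Of 13841 genes tested in HT29, 1874 changed (13.5%), 624 higher and 1250 lower, 341 of them by at least 2-fold (96 higher, 245 lower, limma). The share of higher genes was 33.3%, and 16.3% with TMM scaling. The count was 1203 without WT replicate 1, 1078 without KO replicate 1 and 1229 without KO replicate 2. The 96 genes at least 2-fold higher became 45 without KO replicate 1 and 57 without KO replicate 2, while those lower were 224 and 218.

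**Figure D2:**
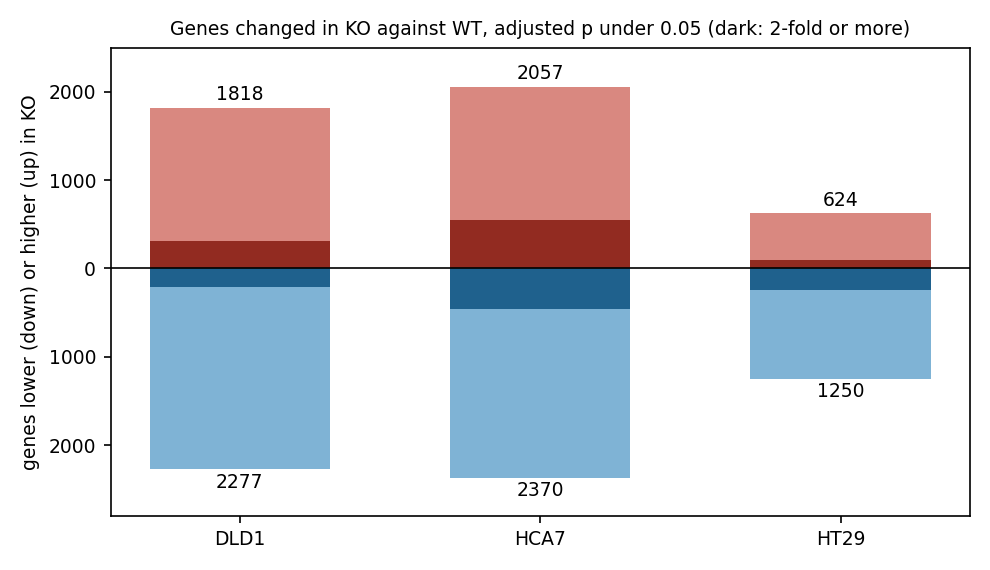
Number of genes called higher and lower in KO than in WT (limma, adjusted p under 0.05) in each line, with changes of at least 2-fold in the dark part of each bar. DLD1 had 1818 higher and 2277 lower, HCA7 2057 and 2370, and HT29 624 and 1250.

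**Figure D3:**
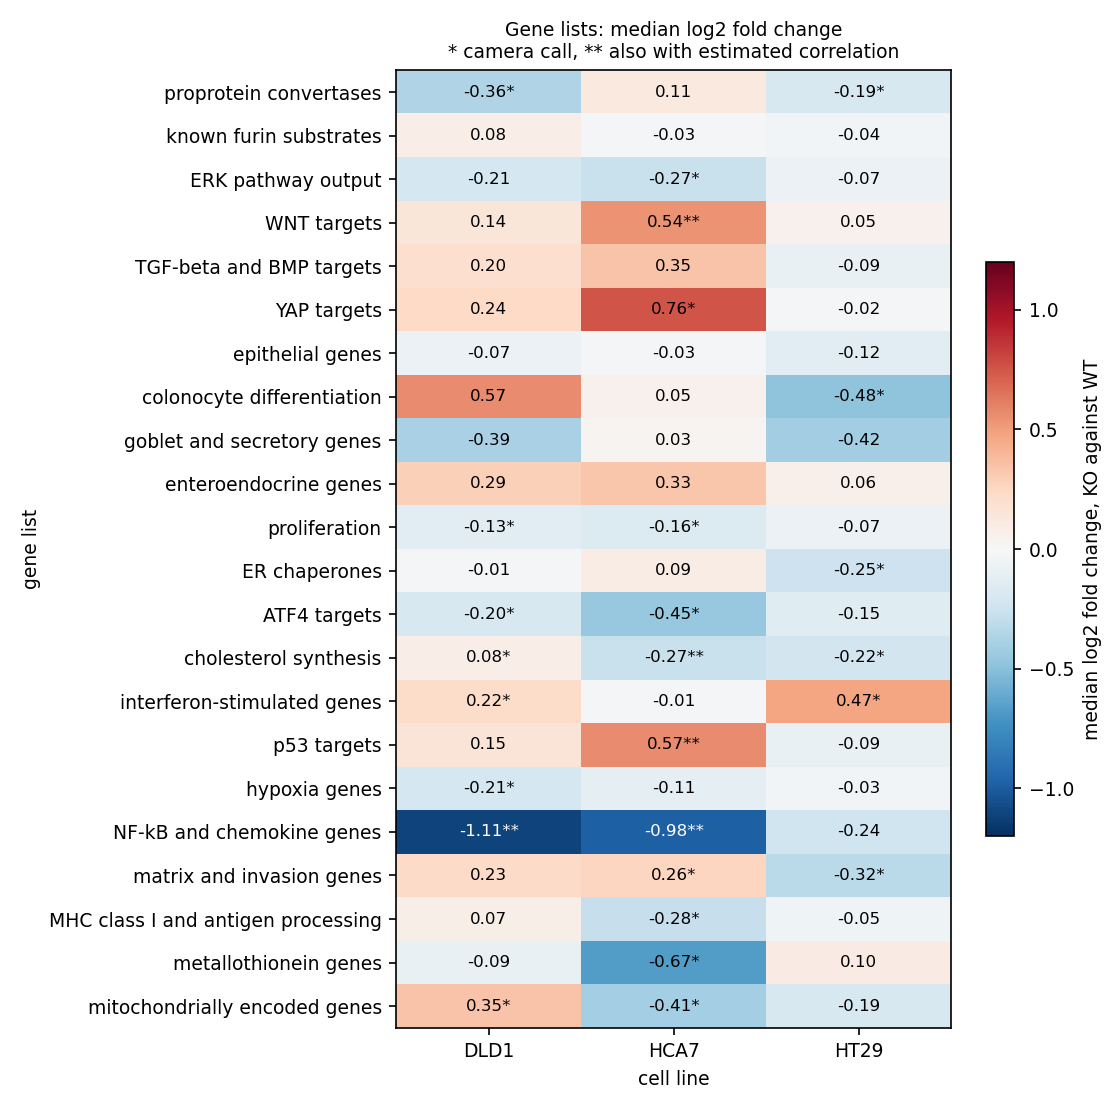
Median log2 fold change of KO against WT for the lists with at least 3 measured members in each line; mesenchymal, fibroblast and blood cell lists are not drawn. One star marks a camera call at an adjusted p under 0.05, and 2 stars a call that also held with an estimated correlation, such as NF-kB and chemokine genes in DLD1 (-1.11) and HCA7 (-0.98).

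**Figure D4:**
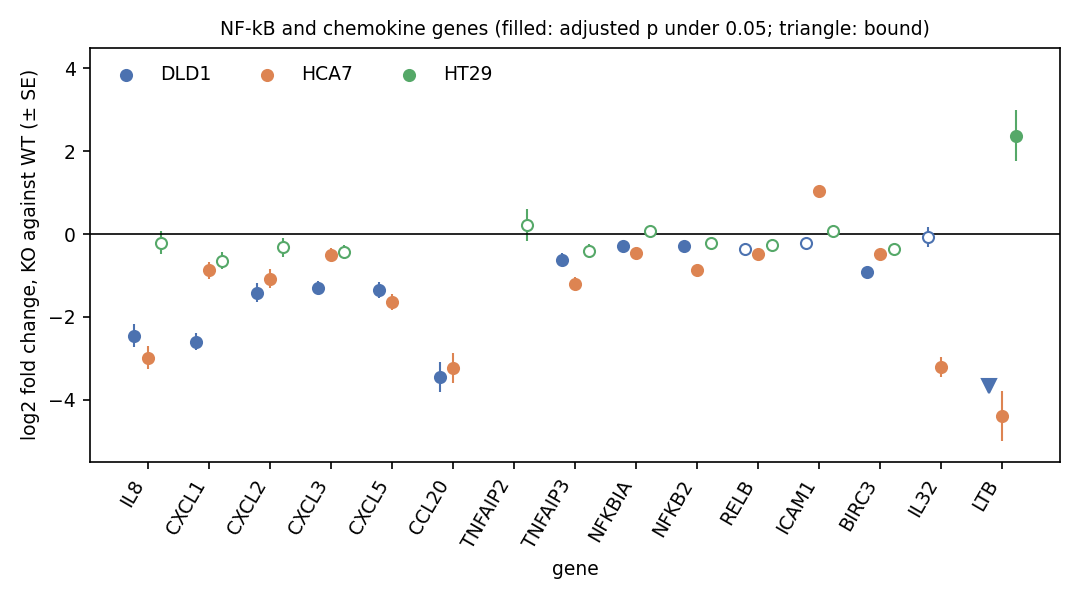
Log2 fold change of KO against WT ± SE for each measured NF-kB and chemokine gene in the 3 lines, filled where the limma adjusted p was under 0.05 and open where it was not; IL8 is CXCL8. The triangle is the bound for LTB in DLD1, with 0 reads in KO, and the chemokine gene CCL20 lies at -3.46 in DLD1.

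The difference between DLD1 and HCA7 asks which KO effects depend on the line. The cholesterol synthesis genes moved apart, with 14 of 18 more positive in DLD1 and 2 more negative, also adjusted over the list alone (INSIG1 1.27 ± 0.07, HMGCS1 1.08 ± 0.07, DHCR7 0.87 ± 0.07). The camera adjusted p was 3.27e-07, and 0.0715 with an estimated correlation. Of 13 mitochondrially encoded genes 12 were more positive in DLD1, also adjusted over the list alone, beside the opposite shifts of their share of reads in these lines (MT-ATP6 1.25 ± 0.14). Here camera gave an adjusted p of 3.27e-07, and 0.377 with an estimated correlation. Of 16 p53 targets 11 were more negative in DLD1 than in HCA7, 13 adjusted over the list alone (BAX -0.68 ± 0.10, PHLDA3 -1.83 ± 0.27, with camera adjusted p = 5.61e-05 and estimated correlation adjusted p = 0.0715). ATF4 targets had 7 of 18 more positive, also adjusted over the list alone (PHGDH 1.97 ± 0.10, with camera adjusted p = 0.00742 and estimated correlation adjusted p = 0.377). Antigen processing genes had 7 more positive and 1 more negative of 12, 9 and 1 adjusted over the list alone (PSMB8 0.73 ± 0.12, with camera adjusted p = 0.00557 and estimated correlation adjusted p = 0.115). The protease inhibitor TIMP1 went from 73.3 and 91.4 to 5.64 and 2.60 in HCA7 and from 1315 and 1302 to 1681 and 1679 in DLD1, a difference of 4.44 ± 0.29, and EPHB6 differed by -4.43 ± 0.13. Of 12708 genes, 3625 differed (28.5%, 1741 more positive and 1884 more negative in DLD1, limma), and FURIN differed by 0.36 ± 0.10 (limma adjusted p = 0.0171).

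The difference between HT29 and HCA7 was called for 14 lists. Of 16 p53 targets 12 were more negative in HT29, 13 adjusted over the list alone and 1 more positive (FAS -1.43 ± 0.14, TP53I3 -1.12 ± 0.13, with camera adjusted p = 1.08e-05 and estimated correlation adjusted p = 0.0599). Of 17 ER chaperones 11 were more negative, 12 adjusted over the list alone (HSPA5 -0.52 ± 0.08, DNAJC3 -0.59 ± 0.10, with camera adjusted p = 0.000121 and estimated correlation adjusted p = 0.192). Matrix and invasion genes had 6 of 10 more negative, 7 adjusted over the list alone and 1 more positive (LAMA3 -2.44 ± 0.09, ITGB6 -2.19 ± 0.14, with camera adjusted p = 0.000481 and estimated correlation adjusted p = 0.0679). Of 10 YAP targets 5 were more negative, also adjusted over the list alone (NT5E -1.68 ± 0.18, with camera adjusted p = 0.00518 and estimated correlation adjusted p = 0.157). Of 10 colonocyte genes 5 were more negative, 6 adjusted over the list alone (CDX2 -1.72 ± 0.15, with camera adjusted p = 0.016 and estimated correlation adjusted p = 0.192).

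The NF-kB and chemokine genes had 5 more positive in HT29 than in HCA7 and 1 more negative of 11, also adjusted over the list alone (IL8 2.77 ± 0.39, NFKB2 0.65 ± 0.09, ICAM1 -0.98 ± 0.14, with camera adjusted p = 0.016 and estimated correlation adjusted p = 0.164). ATF4 targets had 8 more positive and 1 more negative of 18, 11 and 1 adjusted over the list alone (SLC7A11 1.07 ± 0.09, with camera adjusted p = 0.000257 and estimated correlation adjusted p = 0.164). ERK pathway output had 8 more positive and 2 more negative of 17, also adjusted over the list alone (DUSP5 2.32 ± 0.14, ETV4 1.13 ± 0.10, with camera adjusted p = 0.0162 and estimated correlation adjusted p = 0.358). The growth factor TGFB1 rose in HCA7 and fell in HT29, a difference of -3.83 ± 0.15. Of 12546 genes 3207 differed (25.6%, 1546 more positive and 1661 more negative in HT29, limma), 48.2% of them more positive, against 61.4% with upper-quartile and 34.1% with TMM scaling. Without HCA7 KO replicate 2, 1026 were more positive. The FURIN difference of -0.11 ± 0.10 did not pass (limma adjusted p = 0.482).

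The difference between DLD1 and HT29 was called for 6 lists. Of 18 cholesterol synthesis genes 12 were more positive in DLD1, also adjusted over the list alone (INSIG1 1.05 ± 0.07, MSMO1 0.66 ± 0.06, with camera adjusted p = 3.83e-06 and estimated correlation adjusted p = 0.0605). Of 11 NF-kB and chemokine genes 7 were more negative in DLD1, also adjusted over the list alone (CXCL1 -1.96 ± 0.28, IL8 -2.24 ± 0.39, with camera adjusted p = 0.000439 and estimated correlation adjusted p = 0.0605). Matrix and invasion genes had 7 more positive and 1 more negative of 11, 8 and 1 adjusted over the list alone (TNC 5.06 ± 0.31, ITGB6 1.35 ± 0.14, with camera adjusted p = 0.000146 and estimated correlation adjusted p = 0.0605). Mitochondrially encoded genes had 8 of 13 more positive, 10 adjusted over the list alone (MT-CO3 0.77 ± 0.13, with camera adjusted p = 0.000127 and estimated correlation adjusted p = 0.479). ER chaperones had 9 more positive and 1 more negative of 17, 10 and 1 adjusted over the list alone (HSPA5 0.53 ± 0.08, HSP90B1 -0.78 ± 0.09, with camera adjusted p = 0.0237 and estimated correlation adjusted p = 0.516). Known furin substrates had 9 more positive and 3 more negative of 20, also adjusted over the list alone (TGFB1 2.90 ± 0.15, LRP1 1.23 ± 0.10, with camera adjusted p = 0.015 and estimated correlation adjusted p = 0.414). Of 12558 genes 3128 differed (24.9%, 1572 more positive and 1556 more negative in DLD1, limma), 50.3% of them more positive, against 34.3% with upper-quartile and 65.8% with TMM scaling. FURIN differed by 0.47 ± 0.10 (limma adjusted p = 0.00499).

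With an estimated correlation 0 camera calls held in each of the 3 differences. An unadjusted camera p under 0.05 was then seen for 3 lists for DLD1 against HCA7, 6 for HT29 against HCA7 and 3 for DLD1 against HT29. By fry 14, 17 and 12 lists were called. A lost call does not by itself show correlated members, since camera with an estimated correlation also tests on the residual degrees of freedom alone. For NF-kB and chemokine genes in DLD1 the camera p was 5.8e-09 with the preset correlation. It was 0.000816 with the estimated correlation of -0.0397. Matrix and invasion genes for HT29 against HCA7 lost their call at an estimated correlation of -0.0564, and hypoxia genes in DLD1 at -0.00354.

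The average effect takes the 3 lines together, and a gene can be called in it without a change in every line. FURIN changed by -1.35 ± 0.07 (2.54-fold lower, lower in all 6 KO libraries, limma adjusted p = 5.33e-06). The guidance receptor PLXNA2 (-1.56 ± 0.23, limma adjusted p = 0.00526), LCN2 (-1.86 ± 0.37), the membrane protease TMPRSS4 (-1.81 ± 0.44), SLC44A4 (-1.72 ± 0.41), NEO1 (-1.42 ± 0.33), the transporter SLC6A20 (-1.40 ± 0.34) and the adhesion gene PVRL3 (-2.18 ± 0.60, limma adjusted p = 0.0496) were lower. LCN2 in HT29 went from 1609 and 1623 to 1506 and 1535, so its average rests on DLD1 and HCA7. TMPRSS4, SLC44A4, NEO1, SH3BGRL, NR2F1 and APH1B likewise were called in DLD1 and HCA7 and not in HT29, and PVRL3 was called in DLD1 alone. PVRL3 had 121 reads in DLD1 WT and 3 in DLD1 KO (ratio 34.5, 95% interval 11.5 to 170). The amino acid transporter SLC7A8 (1.02 ± 0.12, limma adjusted p = 0.00241), SESN3 (1.31 ± 0.17, limma adjusted p = 0.00404), SH3BGRL (1.95 ± 0.43), FSCN1 (1.65 ± 0.40), the nuclear receptor NR2F1 (1.55 ± 0.39), the epidermal transcription factor GRHL3 (1.04 ± 0.22), ANXA6 (1.02 ± 0.23) and APH1B (1.01 ± 0.19) were higher. With the replicate number as a block, FURIN kept its call (limma adjusted p = 0.00199). The other 15 genes named so far lost theirs, at 0.0598 for SLC7A8 to 0.159 for PVRL3. The sodium-glucose cotransporter SLC5A1 fell further than these genes (-2.82, limma adjusted p = 0.00296) and was called lower in each of the 3 lines. With the block SLC5A1 lost its call on average too (limma adjusted p = 0.0619). The replicate numbers did not pair the libraries, and the block leaves fewer residual degrees of freedom. Calls lost with it therefore do not show a replicate effect.

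Among the lists, 8 of 11 NF-kB and chemokine genes fell on average, 9 adjusted over the list alone (BIRC3 -0.59 ± 0.10, TNFAIP3 -0.74 ± 0.13, CXCL1 -1.37 ± 0.28). With a median of -0.74 the camera adjusted p was 4.09e-06, and 0.226 with an estimated correlation. Of 24 proliferation genes 3 fell, 12 adjusted over the list alone (MCM6 -0.24 ± 0.05, with camera adjusted p = 5.36e-06 and estimated correlation adjusted p = 0.226). Of 18 ATF4 targets 6 fell and 1 rose, 11 and 1 adjusted over the list alone (SLC7A5 -0.35 ± 0.05, MTHFD2 -0.37 ± 0.07, ATF3 0.43 ± 0.07, with camera adjusted p = 5.15e-05 and estimated correlation adjusted p = 0.226). Of 16 p53 targets 4 rose, 6 adjusted over the list alone (GDF15 0.38 ± 0.06, with camera adjusted p = 0.000946 and estimated correlation adjusted p = 0.351). Of 18 cholesterol synthesis genes 4 fell, 6 adjusted over the list alone (SC5D -0.33 ± 0.05, with camera adjusted p = 0.0021 and estimated correlation adjusted p = 0.351). Of 12 WNT targets 4 rose, also adjusted over the list alone, where 1 fell (LGR5 0.39 ± 0.08, with camera adjusted p = 0.00577 and estimated correlation adjusted p = 0.222). Of 17 ERK output genes 4 fell and of 15 interferon-stimulated genes 3 rose, also adjusted over the list alone (IER3 -0.44 ± 0.09, IFITM3 0.57 ± 0.13). Camera adjusted p-values were 0.00993 and 0.0267, and 0.226 and 0.275 with an estimated correlation. The genes named with these lists were not called on average with the replicate number as a block (adjusted p = 0.0703 for GDF15, the lowest, to 0.123 for LGR5). In the average 0 camera calls held with an estimated correlation, where 3 lists had an unadjusted camera p under 0.05, and fry called 11.

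Of 12069 genes tested in all 3 lines 839 changed on average (6.95%; 344 higher, 495 lower, limma), 51 of them by at least 2-fold (24 higher, 27 lower). The share of higher genes was 41.0%, and 26.9% with upper-quartile and 25.7% with TMM scaling. Its count was 9 with the replicate number as a block, and leaving out any 1 of the 8 DLD1 and HCA7 libraries gave 296 (without HCA7 KO replicate 1) to 448. Without HT29 KO replicate 1, 312 were lower.

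The calls of the lines overlapped in part. Over all genes tested in both lines of a pair, the fold changes were nearly uncorrelated. Pearson (and Spearman) correlations were 0.052 (0.106) for DLD1 and HCA7, 0.061 (0.042) for HT29 and HCA7 and 0.028 (0.025) for DLD1 and HT29. The matched counts below allow for expression alone, not for the spread of a gene, which the lines share in the fit. DLD1 and HCA7 shared 451 higher genes, against 258 for genes matched in expression, and 587 lower genes, against 484. HT29 and HCA7 shared 126 higher (87.0 by matching) and 299 lower genes (238 by matching). DLD1 and HT29 shared 147 higher genes (83.0 by matching) and 243 lower ones (256 by matching, with an odds ratio stratified by expression of 0.92, 95% interval 0.79 to 1.08). Genes called in opposite directions numbered 649 for DLD1 and HCA7 (618.2 by matching), 397 for HT29 and HCA7 (279 by matching) and 334 for DLD1 and HT29 (265 by matching). In all 3 lines 45 genes were called higher and 69 lower, against 12.4 and 61.6 for genes matched in expression (11.5 and 36.2 without matching). Of the 6662 genes called in at least 1 line, among those tested in all 3, 4291 (64.4%) were called in 1 line alone.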

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

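The values here are differences between 2 lines in the KO effect, each tested as an interaction in limma or camera; the tests of clones or cultures, of unedited cells and of the size factors and single libraries behind the NF-kB result were chosen only after those results were seen.

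Between DLD1 and HCA7, 3625 genes differed. MYADM (8.91), which had 1 read in HCA7 KO so that its fitted value depends on the pseudocount, ARMCX3 (6.10) and the protease inhibitor TIMP1 (4.44) were more positive in DLD1, and the receptor EPHB6 (-4.43), SOGA2 (-4.17) and the calcium sensor VSNL1 (-4.08) more negative. FURIN differed by 0.36. Camera adjusted p-values were 0.00742 for ATF4 targets, 3.27e-07 for cholesterol synthesis, 5.61e-05 for p53 targets, 0.00557 for MHC class I and antigen processing and 3.27e-07 for mitochondrially encoded genes. With estimated correlation all 5 calls were lost, at 0.377, 0.0715, 0.0715, 0.115 and 0.377 in that order.

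Between HT29 and HCA7, 3207 genes differed. MYADM (8.50), ATP2C2 (7.08) and GRAMD1B (6.71) were more positive in HT29, with fitted values that depend on the pseudocount: in HCA7 KO the first 2 had 1 read each and GRAMD1B had 0, against 338 in WT (at least 113-fold lower). More negative were FAM84A (-5.27), EPHB6 (-4.33) and the nuclear receptor NR2F2 (-3.90). FAM84A had 100 reads in HT29 WT and 2 in KO (ratio 39.5, 95% interval 10.7 to 331), so its fitted value depends on the pseudocount too. Camera adjusted p-values were 1.08e-05 for p53 targets, 0.000121 for ER chaperones, 0.000257 for ATF4 targets, 0.000481 for matrix and invasion genes, 0.00518 for YAP targets, 0.016 for colonocyte genes, 0.016 for NF-kB and chemokine genes and 0.0162 for ERK output. With estimated correlation these 8 calls were lost, at 0.0599, 0.192, 0.164, 0.0679, 0.157, 0.192, 0.164 and 0.358 in that order. The preset correlation gave 0.0244 for mitochondrially encoded genes, 0.0325 for WNT targets, 0.034 for interferon-stimulated genes, 0.034 for antigen processing, 0.0454 for TGF-beta and BMP targets and 0.0454 for proliferation, with estimated correlation adjusted p-values of 0.481, 0.164, 0.261, 0.164, 0.309 and 0.484 for these last 6.

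Between DLD1 and HT29, 3128 genes differed. The matrix glycoprotein TNC (5.06) and the elongation factor EEF1A2 (4.41) were more positive in DLD1, and the nuclear receptor cofactor NRIP1 (-5.27; 184 reads in DLD1 WT and 3 in KO), the stem cell marker PROM1 (-3.77; 73 and 2 reads) and the protease TMPRSS4 (-3.61) more negative. In DLD1 the ratio of WT to KO was 52.5 for NRIP1 (95% interval 17.7 to 257) and 31.3 for PROM1 (95% interval 8.35 to 263). The fitted values of these genes depend on the pseudocount. FURIN differed by 0.47. Camera adjusted p-values were 3.83e-06 for cholesterol synthesis, 0.000127 for mitochondrially encoded genes, 0.000146 for matrix and invasion genes, 0.000439 for NF-kB and chemokine genes, 0.015 for known furin substrates and 0.0237 for ER chaperones. In camera with an estimated correlation these 6 calls were lost, at adjusted p = 0.0605, 0.479, 0.0605, 0.0605, 0.414 and 0.516 in that order. That correlation was -0.0494 for matrix and invasion genes and 0.00948 for NF-kB genes, below the preset 0.01. A higher correlation is thus not why those calls were lost.

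In DLD1, HCA7 and HT29 4095, 4427 and 1874 genes changed, and 64.4% of the genes called were called in 1 line alone. Gained or lost chromosome segments as the whole cause are argued against, since 87.5% of the placed calls in DLD1, 88.2% in HCA7 and 76.5% in HT29 were left, with their sign, after the running median of the 50 nearest genes was taken off; shorter segments are not excluded. Depth is argued against as well: with each library thinned to 10244000 reads, at least 79.2% of the calls of a line were made again. For the average effect the splits of the libraries decide nothing (839 genes with the real one, highest other 392). Of the 100 drawn 96 gave 0, where mixing KO and WT in a line puts their difference into the residual. The split with 392 also mixed them in at least 1 line, so mixing did not always give 0. The highest other split drawn that kept them apart gave 335. Only 4 possible splits keep them apart in every line, too few for a share under 0.05. Differences between clones or cultures unrelated to furin and effects of furin that depend on the line both may give calls in 1 line alone. They cannot be told apart: the labels do not say how many clones or cultures the 1 KO group of each line holds.

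The NF-kB and chemokine genes were lower in DLD1 and HCA7. The authors' size factors are argued against, since the highest list median in these lines was -0.97 under 3 other scalings, and so is 1 outlying library, with -0.97 as the highest median without any 1 library. In HT29 the list was not called by camera, though fry called it lower (fry adjusted p = 0.0268). A fall hidden by low expression stays open: the 7 members with a mean of at least 50 there had a median of -0.21. A bound of -0.5, set beforehand to exclude that explanation, proved wrong once the result was seen, because the 6 of these members tested in DLD1 and HCA7 as well had medians of only -0.33 and -0.49 there, where the list fell, and -0.21 in HT29. A response of NF-kB genes to furin loss in DLD1 and HCA7 is an untested candidate explanation, as is a difference between cultures.

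FURIN mRNA was lower but present in the KO libraries, at up to 47.7% of the WT level. A deletion that takes most of the neighbouring genes is argued against, since the lowest median of the 8 nearest tested genes over the 3 lines was -0.0778. A median of 8 genes cannot exclude a deletion of only a few of them. Of these genes BLM in DLD1 (-0.22) and IQGAP1 (-0.29) and MAN2A2 (-0.22) in HT29 were called lower. CRTC3 (0.31) and RCCD1 (0.32) in DLD1 were called higher. Unedited cells among the KO cells, and edited transcripts that are made and partly decay, both may leave FURIN reads and cannot be told apart from gene totals. No biological explanation was tested.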

How the results depend on the processing

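The edgeR test, TMM scaling, the pseudocounts, the filter over all libraries, TREAT and the convertase list without FURIN were chosen as alternatives after seeing the data; the others were planned. Of 365 results for named genes, 8144 of 8760 alternative values kept direction and call, 616 kept the direction and lost the call, and 0 reversed. With the replicate block alone 73 of the 365 lost the call. Most of these genes were named because they were called, so few reversals could occur. Leaving out a library of another line also does not change a fold change within a line. Of 59 list calls, 797 of 885 alternative values kept direction and call, 88 lost the call and 0 reversed. Of the 88, 54 were lost with an estimated correlation, where camera also tests on fewer degrees of freedom. The average effect, with 839 genes, gave 455 with no low-value filter, 1360 with DESeq2, 9 with a replicate block and 4097 as the mean of the 3 within-line effects, which leaves the spread between lines out. The replicate numbers did not pair the libraries (across 10502 genes, correlations of the deviations were -0.0536 in DLD1, -0.0276 in HCA7 and 0.0728 in HT29), and with the block 3821, 4174 and 1589 genes were called in the 3 lines. In HT29, 512 genes changed at least 2-fold with no filter, against 341; the cause was not tested.

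With an estimated correlation camera called 1 list in DLD1, 4 in HCA7, 0 in HT29, 0 in each of the 3 differences and 0 in the average, where 6 lists in HT29, 3, 6 and 3 in the differences and 3 in the average had an unadjusted p under 0.05; fry, which does not compare a list with other genes, called 19 in DLD1, 11 in HT29, 14 for DLD1 against HCA7 and 12 for DLD1 against HT29.

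Without 1 library in turn, called genes ranged from 2255 (without DLD1 KO replicate 2; 2572 without WT replicate 2, 2685 without KO replicate 1) to 4388 in DLD1, from 2751 (without HCA7 KO replicate 1; 2831 without KO replicate 2) to 4690 in HCA7 and from 1078 (without HT29 KO replicate 1; 1203 without WT replicate 1, 1229 without KO replicate 2) to 1823 in HT29. Differences ranged from 2537 to 3877 for DLD1 against HCA7, 2193 to 3353 for HT29 against HCA7 and 2147 to 3242 for DLD1 against HT29. The average ranged from 296 (without HCA7 KO replicate 1) to 1077; without HCA7 KO replicate 2 it was 315, without HCA7 WT replicates 1 and 2 in turn 393 and 418, without DLD1 WT replicates 1 and 2 414 and 448, and without DLD1 KO replicates 1 and 2 393 and 397. Genes changed at least 2-fold ranged from 403 to 534 in DLD1, 849 to 1019 in HCA7 and 269 to 343 in HT29, and FURIN from -1.11 to -1.03, -1.49 to -1.37 and -1.62 to -1.46. Lists called ranged from 5 (without DLD1 WT replicate 2 or KO replicate 1) to 10 in DLD1, 11 to 13 in HCA7, 6 to 11 (without HT29 WT replicate 1) in HT29, 9 (without HCA7 KO replicate 1) to 15 for HT29 against HCA7, 5 to 8 for DLD1 against HT29, 7 to 10 for the average, and were 5 throughout for DLD1 against HCA7. At these depths and 2 libraries per group, 1.3-fold changes were called in 50% of simulated cases in DLD1, so smaller changes were often not detectable.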

Other observations

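The zinc finger test and the genes named as called in all 3 lines were chosen only after their values were seen.

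In HT29, zinc finger genes of chromosome 19, many of which encode KRAB-type repressors of transcription, were lower in KO. Of 175 tested genes with a ZNF symbol on that chromosome 54 fell and none rose, and 154 had a value below 0 (median -0.36; camera p = 1.9e-15, and p = 0.00153 with an estimated correlation). The 225 ZNF genes on other chromosomes had a median of 0.02, with 12 lower and 9 higher, and the 666 other genes of chromosome 19 a median of -0.05, with 99 lower and 30 higher. In DLD1 the 167 ZNF genes of chromosome 19 had a median of 0.10, with 5 lower and 15 higher (camera p = 0.0437, and p = 0.174 with an estimated correlation), and in HCA7 the 169 had a median of -0.04, with 17 lower and 7 higher (camera p = 0.434, and p = 0.603 with an estimated correlation). These 3 tests were not adjusted for one another. Along chromosome 19 in HT29, 30 genes from RPSAP58 to ZNF599 had a median of -0.29, with 16 called lower, and 34 genes from ZNF549 to CENPBD1P1 a median of -0.28, with 10 called lower; the order is that of GENCODE v29.

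Among the genes called in 1 direction in all 3 lines, the glucose transporter SLC5A1 changed by -1.95 in DLD1, -4.29 in HCA7 and -2.20 in HT29. Also lower were the amino acid transporters SLC1A5 (-0.17, -0.45 and -0.37 in DLD1, HCA7 and HT29) and SLC38A1 (-0.33, -0.25 and -0.27), the transferrin receptor TFRC (-0.37, -0.49 and -0.40), asparagine synthetase ASNS (-0.22, -1.14 and -0.25) and S100A4 (-0.52, -0.80 and -0.92). Higher in each line were YPEL3 (0.88, 0.70 and 0.91), BAIAP3 (0.83, 1.69 and 0.99), the semaphorin receptor PLXND1 (1.42, 0.67 and 0.71), the actin-binding GSN (0.96, 0.38 and 0.41) and the growth factor BMP4 (0.34, 1.21 and 0.23). Each value is from 2 KO and 2 WT libraries. The 69 genes lower in all 3 lines were near the 61.6 for genes matched in expression. For the 45 higher genes matching gave 12.4.

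The epithelial, goblet, TGF-beta and enteroendocrine lists were not called by camera in any of the 3 lines, and counts adjusted over the list alone are given where they differ. Of 15 epithelial genes 3 rose and 6 fell in DLD1 (4 and 6 adjusted over the list alone; KRT18 -0.67 ± 0.06), 1 rose and 1 fell in HCA7 and 4 fell in HT29 (1 rose and 6 fell adjusted over the list alone). Their camera adjusted p-values were 0.234, 0.928 and 0.0699. Goblet and secretory genes had 1 higher and 4 lower of 9 in DLD1 (1 and 5 adjusted over the list alone), 2 and 3 of 7 in HCA7 (MUC5AC 1.66 ± 0.11, CREB3L1 -3.58 ± 0.23) and 4 lower of 13 in HT29 (FCGBP -1.47 ± 0.32). Camera adjusted p-values were 0.133, 0.812 and 0.0699, and in HCA7 the median was 0.03 and the mean -0.79. TGF-beta and BMP targets had 5 higher and 1 lower of 12 in DLD1 (5 and 5 adjusted over the list alone) and 6 and 3 of 12 in HCA7 (TGFBI 1.41 ± 0.06), with camera adjusted p = 0.252 and 0.165. Of the enteroendocrine genes the chaperone SCG5 rose in DLD1 (1.21 ± 0.27, 1 of 3 measured; camera adjusted p = 0.375) and HCA7 (1.11 ± 0.27, 1 of 3; camera adjusted p = 0.498), and RFX6 in HT29 (1.59 ± 0.42, 1 of 4; camera adjusted p = 0.728).

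Few markers of other cell types were expressed highly enough to be tested. The mesenchymal list had 3 measured members in DLD1, none called (camera adjusted p = 0.848), and 2 in HCA7, of which PRRX1 rose (1.97 ± 0.40), and 2 in HT29, none called. The fibroblast list had 2 measured members in each line and no set test: COL1A1 fell in HCA7 (-1.84 ± 0.40) and LUM in HT29 (-2.08 ± 0.34), while THY1 and POSTN were listed at 0 in all 12 libraries. Of the blood cell markers CD3E, CD3D, MS4A1 and PECAM1 were listed at 0 in all 12 libraries, and none of the 3 measured in DLD1 (camera adjusted p = 0.848), the 1 in HCA7 or the 3 in HT29 (camera adjusted p = 0.763) was called; the lysozyme gene LYZ was at 49516 and 45168 in HT29 WT and 54818 and 57200 in HT29 KO.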
